A study of Mus with 12 samples.

How the data were processed

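Gene expression was measured by RNA sequencing in 12 libraries, whose source is given in the labels as primary mouse peritoneal macrophages, which are macrophages taken from the abdominal cavity. The labels' protocol text speaks of RNA of a specific adipose type, which does not match that source. Per the labels, 6 libraries came from wild-type (WT) and 6 from knockout (KO) cells, and 3 libraries of each genotype carry the treatment label oxLDL, for oxidised low-density lipoprotein, a modified form of the particle that carries cholesterol in blood. The titles of the libraries with that label say LDL and not oxLDL, and which of these was given could not be checked in the table. The remaining 3 libraries of each genotype carry no treatment label and are called untreated here, so the design has 4 groups with n = 3 libraries each. The labels give the genotype as KO without a gene, and the series title names WEE1. Poly(A) RNA was fragmented and sequenced in pairs on an Illumina NovaSeq instrument, per the labels' protocols. Reads were aligned with HISAT2 version 2.0 and Bowtie version 0.12.2 to build mm8, per the submitters' processing notes. The deposited coordinates were compared with the genes of GRCm38.p6: 99.93% of the 21990 genes matched by Entrez identifier overlapped their annotated position, so positions are given here as GRCm38 and not as mm8. The tool that counted reads, its gene annotation and its strand setting are not given in the sources used here, so reads of overlapping, antisense or near-identical genes could not be assigned apart.

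The deposited table holds 27294 genes with raw read counts and FPKM (fragment counts divided by transcript length and by library size) for each of the 12 libraries, per the file headers. The FPKM values were made by the authors before deposit, and the counts were the authors' own per-gene read counts. All per-sample columns of the table were used. In 54 rows the symbol repeated that of an earlier row, and each row with a shared symbol kept its own Ensembl identifier. Library totals of the counts ran from 53588814 to 76809931. No pair of libraries held identical values.

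The planned test was limma on log2(FPKM + 1), with edgeR in its place if raw counts were in the table. Raw counts were there, so edgeR's quasi-likelihood test version 4.0.16 was run in R 4.3.3 on the counts, with TMM scaling and the filterByExpr filter, which kept 17291 genes. The 4 groups were fitted together with no block, with a common dispersion of 0.0279 and 5.57 prior degrees of freedom. The 5 contrasts were oxLDL against untreated in WT, the same in KO, KO against WT untreated, KO against WT with oxLDL, and the genotype by oxLDL interaction (the oxLDL change in KO minus that in WT). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Log2 fold changes are edgeR's fitted values on the TMM scale with their standard errors (SE). FPKM values rest on library size without TMM, so a log2 change need not match the ratio of the FPKM means beside it. Where all 3 libraries of a group held 0 counts, the fold is a lower bound against a floor of 3 counts over the group, scaled by effective library size. Ratios with 1 to 3 counts have 95% intervals for counting error only, since reads are not independent molecules. FPKM values are given as mean ± SD over n = 3 libraries. Nothing in the labels says whether replicates came from separate animals, so every p-value measures the spread between these libraries. With 3 libraries per group, an exact rank or permutation test of a single value cannot go below p = 0.1, so single values rest on the model fitted across all genes.

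Simulated counts drawn from the real means, library sizes and spread were run through the same tests. In them 200 genes, each with a mean of at least 20 counts, were changed in either direction. Per contrast, edgeR's test called 38.8 to 56.7% of the genes simulated at 1.5-fold, with 46.3% for oxLDL in KO. It called 64.2 to 71.6% of those at 2-fold and 78.8 to 89.4% of those at 4-fold, and 1.5 to 7.43% of its calls were genes left unchanged. With so few genes changed, these figures do not test the scaling under the broad changes reported here. A simulated list of 20 genes raised 1.5-fold was found by camera and by fry, and neither called any of the 34 unchanged lists.

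Gene lists were fixed from general knowledge before the data were examined, as were the contrasts, the rule for naming genes and most of the other settings tried. The 35 lists covered cytokines and chemokines, NF-κB feedback targets, NF-κB and Toll-like receptor pathway components, the inflammasome, interferon-stimulated genes, class II antigen presentation, scavenger and uptake receptors, cholesterol efflux and liver X receptor targets, cholesterol biosynthesis, fatty acid synthesis, PPAR targets with lipid storage and oxidation, NRF2 and oxidative stress, unfolded protein and integrated stress response, S phase, G2/M phase, WEE1 and other regulators of cyclin-dependent kinases, p53 and DNA damage, alternative activation, efferocytosis, matrix proteases, glycolysis and hypoxia, immediate early and heat shock genes, mitochondrially encoded genes, macrophage core genes, large peritoneal macrophages, monocyte-derived macrophages, B cells, T and NK cells, neutrophils, mast cells, eosinophils, mesothelium and fibroblasts, dendritic cells, platelets and erythroid cells, and housekeeping genes. Each list was tested with limma's camera (version 3.58.1) with a preset correlation of 0.01, again with an estimated correlation, and with fry; all were two-sided, and p was adjusted over the 35 lists and 5 contrasts together. Members that passed were also counted after adjustment over the list alone, and that count is given beside a printed count from which it differs. Counts of called members are to be read against the share called among all genes tested. It was 51.2% for oxLDL in WT, 0.0116% for oxLDL in KO and 41.7% for the interaction. For KO against WT it was 31% untreated and 57.9% with oxLDL.

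Genes named for each contrast were Wee1 and 9 others fixed in advance (Rela, Nfkb1, Tnf, Il1b, Il6, Ccl2, Cd36, Abca1 and Plin2). To these were added the 8 largest rises and the 8 largest falls among called genes with a mean of at least 1 FPKM in the higher group and, except for the interaction, no overlap between the groups. From each list with at least 3 called members or a passed list test, the 2 largest rises and the 2 largest falls were added. Symbols of predicted, ribosomal protein, pseudogene or clone type were left out of the largest changes. Where fewer than 5 genes were called, the 5 smallest unadjusted p in each direction are given as values. Some genes that the rule names are not reported here.

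The alternatives were limma on log2(FPKM + 1) with its own variants, DESeq2 version 1.42.0, edgeR with library totals alone or with no filter, only the 6 libraries of a contrast, replicate blocks, stricter thresholds, and leaving out each library in turn. Correlations of fold changes are across genes, which are not independent replicates, so they carry no p.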

Results

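RNA from mouse primary peritoneal macrophages, per the labels, was sequenced in 12 libraries. The genotypes were wild type (WT) and knockout (KO), each without treatment or with oxidised low-density lipoprotein (oxLDL, per the treatment label; the sample titles say LDL), with n = 3 libraries in each of the 4 groups. Summed gene counts per library ran from 53588814 to 76809931, and WT replicate 2 was the shallowest in both treatment groups, with 54574550 counts untreated and 53588814 with oxLDL. Between 18679 and 20522 genes had counts in a library, and 17291 genes were tested. The series title names WEE1, a kinase that restrains entry into mitosis, together with the NF-κB subunit p65 and inflammation. The comparisons below therefore ask how the macrophage response to oxLDL differed between genotypes.

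Wee1 was lower in KO libraries than in WT but not absent from them. Wee1 (ENSMUSG00000031016, chromosome 7, 110122046 to 110143286 on GRCm38, plus strand) had 3.05 ± 0.23 FPKM in untreated WT and 1.48 ± 0.23 FPKM in untreated KO libraries (SD, n = 3), which is 48.7% of the WT mean. It had 1.62 ± 0.17 FPKM in WT with oxLDL and 1.38 ± 0.19 FPKM in KO with oxLDL. All 12 libraries had between 328 and 851 Wee1 counts. The log2 difference of KO against WT was -0.93 ± 0.14 (SE) untreated (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.000139) and -0.53 ± 0.14 with oxLDL (adjusted p = 0.00587). These fitted values are on the TMM scale, so they need not match the ratios of the FPKM means. The difference with oxLDL no longer passed with library totals alone (-0.23) or with limma on FPKM (-0.14). Wee1 fell with oxLDL in WT, at -0.50 ± 0.14 (adjusted p = 0.00864 in edgeR's test), so KO libraries at 1.22 to 1.63 FPKM overlapped the WT libraries with oxLDL at 1.44 to 1.78 FPKM. Gene-level counts do not show which exon a knockout removes, so these values are a weak check of the genotype labels.

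**Figure D1:**
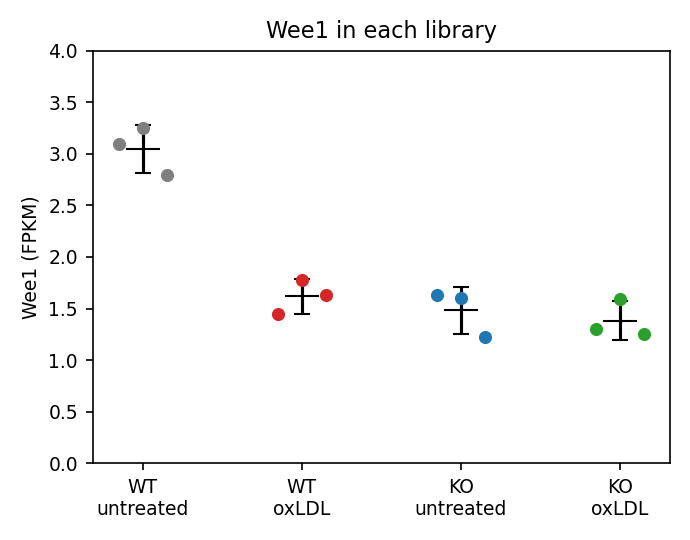
Wee1 expression in FPKM (vertical axis) in each of the 12 libraries, by genotype and treatment (horizontal axis); points are libraries and bars are the mean ± SD of 3. Untreated WT libraries lie at 2.8 to 3.25 FPKM and untreated KO libraries at 1.22 to 1.63 FPKM.

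Across all genes, WT libraries with and without oxLDL lay far apart, while KO libraries lay together whatever their treatment label. The first principal component of log2 expression held 61% of the variance and placed WT with oxLDL at -148.6 to -139.8, untreated WT at -14.7 to -11.9, untreated KO at 78.8 to 81.6 and KO with oxLDL at 74.1 to 79.5. The second component, with 9.26% of the variance, held untreated WT apart at 54.1 to 68.6. The 10 most abundant genes took 10.3% of counts in WT with oxLDL, 14.1 to 14.3% in untreated WT and 17.3 to 18.1% in KO libraries. TMM factors were 0.832 to 0.843 in WT with oxLDL and 1.1 to 1.125 in untreated WT. With library totals alone, the median gene shifted by -0.43 log2 with oxLDL in WT and by 0.33 for KO against WT with oxLDL, and TMM moved these medians to -0.06 and 0.05. The untreated KO difference shifted by -0.11 with library totals and the interaction by 0.44. All changes below are relative to the TMM scale.

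**Figure D2:**
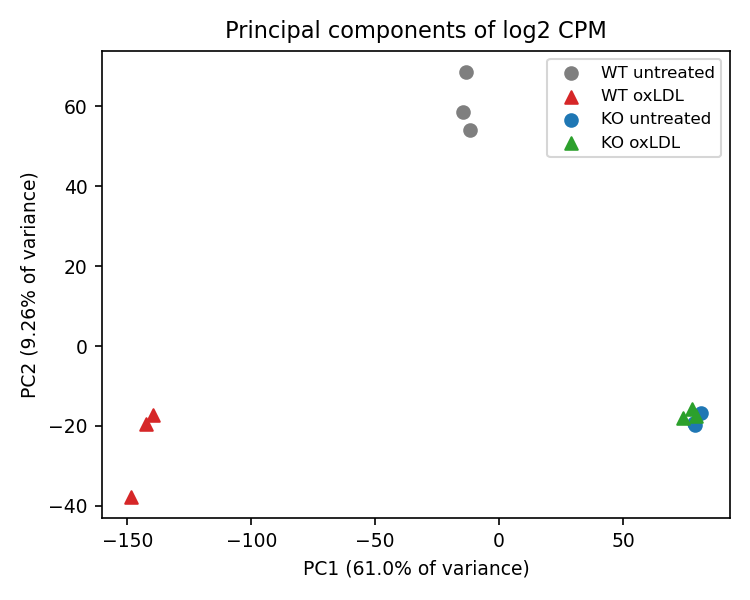
Position of each of the 12 libraries on the first (horizontal axis) and second (vertical axis) principal components of log2 expression; colours mark the 4 groups. WT libraries with oxLDL lie at -148.6 to -139.8 on the first component, and KO libraries of both treatments at 74.1 to 81.6.

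The first comparison asked what oxLDL changed in WT macrophages, and inflammatory genes rose strongly while lipid handling genes went both ways. Il1b, which encodes the cytokine interleukin-1β, rose from 3.71 ± 0.45 to 391 ± 9.4 FPKM (SD, n = 3), a log2 change of 7.13 ± 0.24 (SE). Tnf, the gene of tumour necrosis factor, rose from 44 ± 2.6 to 798 ± 27 FPKM (4.59 ± 0.11), and Nos2, which makes nitric oxide, from 3.83 ± 0.48 to 802 ± 8.4 FPKM (8.11 ± 0.38). Il6 rose by 7.38 ± 0.37 log2 and Ccl2, a chemokine that recruits monocytes, by 4.99 ± 0.08. The NF-κB subunit genes Rela (p65) and Nfkb1 (p50) rose by 1.28 ± 0.07 and 1.86 ± 0.05. Cd36, a receptor through which macrophages take up oxLDL, fell from 207 ± 8.2 to 124 ± 4.1 FPKM. Its fitted change was smaller than the FPKM ratio, at -0.34 ± 0.05 on the TMM scale. Abca1, which exports cholesterol, rose by 0.61 ± 0.04. Plin2, which coats lipid droplets, fell by 0.14 ± 0.04.

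The other largest rises with oxLDL in WT included the vasoconstrictor peptide gene Edn1 (8.18 ± 0.29 log2), Shisa3 (6.98 ± 0.68), a membrane protein that dampens WNT signalling, and Csf3 (6.96 ± 0.28), a growth factor for neutrophils. The cytokine genes Il1f6 and Il22 went from 0 counts in the untreated group to 307 and 279 counts, at least 138-fold and at least 125-fold higher. The largest falls included Galnt9 (-5.80 ± 0.39) and St6gal1 (-5.02 ± 0.09), which add sugars to proteins, and Slc27a6 (-5.15 ± 0.39), a fatty acid transporter. Arhgap19 (-4.73 ± 0.06), Nlrp1b (-4.72 ± 0.14), an inflammasome sensor, Deptor (-4.34 ± 0.14), a brake on mTOR, and Tmem154 (-4.31 ± 0.05) fell as well. Trav14n-3, a T cell receptor segment, had 99 counts without and 2 with oxLDL, a ratio of 0.0272 (95% counting interval 0.00325 to 0.101).

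Every tested member of 3 lists rose with oxLDL in WT: 29 of 29 cytokines and chemokines, 37 of 37 NF-κB feedback targets and 43 of 43 interferon-stimulated genes, with the same counts when adjusted over the list alone. Cd40 (4.33 ± 0.11), a costimulatory receptor, and Il1rn (3.89 ± 0.07), the interleukin-1 receptor antagonist, rose among the feedback targets, and Isg20 (4.88 ± 0.12) and Mx1 (3.92 ± 0.10), which restrict viruses, among the interferon-stimulated genes. Camera gave these 3 lists adjusted p = 2.01e-45, 1.86e-69 and 3.07e-77, and adjusted p = 0.00343, 3.27e-05 and 0.00295 with an estimated correlation. Of 32 pathway components 24 rose and 4 fell (25 and 4 adjusted over the list alone; camera adjusted p = 1.73e-14, and 0.00217 with an estimated correlation). Here Cd14 (2.43 ± 0.05), a co-receptor for bacterial lipids, and the brake Irak3 (2.31 ± 0.05) rose, while the receptor Tlr4 fell (-1.03 ± 0.06). Of 14 inflammasome genes 9 rose and 4 fell, the same adjusted over the list alone (camera upward, adjusted p = 0.00703, and adjusted p = 0.0687 with an estimated correlation); Nlrp3 rose (2.89 ± 0.05) and the ATP receptor P2rx7 fell (-1.17). Of 10 class II antigen presentation genes 4 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.316), with Cd86 at 2.50 ± 0.09. This is near the 51.2% called among all genes tested. Of 23 immediate early and heat shock genes 17 rose and 3 fell, or 17 and 4 adjusted over the list alone (camera adjusted p = 1.03e-05, and 0.0119 with an estimated correlation), with Hspa1b (5.11) and Hspa1a (4.62), which refold damaged proteins, among the rises and Klf2 (-1.14) among the falls.

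Lipid lists went both ways with oxLDL in WT, and the counts per list were the same adjusted over the list alone. Of 22 cholesterol efflux and liver X receptor genes 12 fell and 8 rose (camera downward, adjusted p = 0.0368, and adjusted p = 0.287 with an estimated correlation). Ch25h, which makes 25-hydroxycholesterol, rose by 5.79 ± 0.20 and the receptor gene Nr1h3 by 0.99, while Cyp27a1 (-2.04 ± 0.15), which makes 27-hydroxycholesterol, and Arl4c (-1.93) fell. Of 24 cholesterol biosynthesis genes 11 fell and 4 rose (camera adjusted p = 0.268), with Dhcr7, an enzyme of its final steps, at -3.05 ± 0.13. Of 12 fatty acid synthesis genes 7 fell and 1 rose (camera downward, adjusted p = 0.00865, and adjusted p = 0.209 with an estimated correlation), among them the desaturase genes Scd2 (-1.74) and Fads1 (-1.57). Of 26 PPAR and lipid storage genes 14 fell and 8 rose (camera adjusted p = 0.0662). The lipid regulator Pparg fell by 3.09 ± 0.08 log2 and the inhibitory receptor gene Cd300a by 2.73, while Dgat2 (4.89 ± 0.30), which makes triglycerides, and Hilpda (1.96) rose. Of 16 scavenger and uptake genes 8 rose and 7 fell (camera adjusted p = 0.191), with Cav1 (2.83), a coat protein of caveolae, and Scarf1 (2.02) up and Clec7a (-1.03) and Lrp1 (-0.79) down. Of 28 NRF2 and oxidative stress genes 14 rose and 10 fell (camera upward, adjusted p = 0.0106, and adjusted p = 0.338 with an estimated correlation), with the cystine transporter gene Slc7a11 at 3.09 and the haem-degrading Hmox1 at 1.42.

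With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 8848 genes changed with oxLDL in WT, 4140 up and 4708 down, and 3510 of them by at least 2-fold. Adjusted p was 7.08e-10 for Rela, 2.16e-13 for Tnf, 6.09e-12 for Il1b, 5.84e-15 for Ccl2, 2.2e-05 for Cd36, 1.62e-08 for Abca1 and 0.0173 for Plin2 in edgeR's test. The groups of 3 libraries did not overlap for 10136 genes (58.6%, against 10% by chance). The split of directions rested on the scaling: 46.8% of called genes were higher with TMM, 21.1% with library totals alone and 21.5% with limma on FPKM. The changes of Abca1 and Plin2 no longer passed under some scalings, at 0.08 for Abca1 with quantile normalization and -0.10 for Plin2 with DESeq2, and Plin2 did not pass without WT replicate 1 with oxLDL (-0.11).

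**Figure D3:**
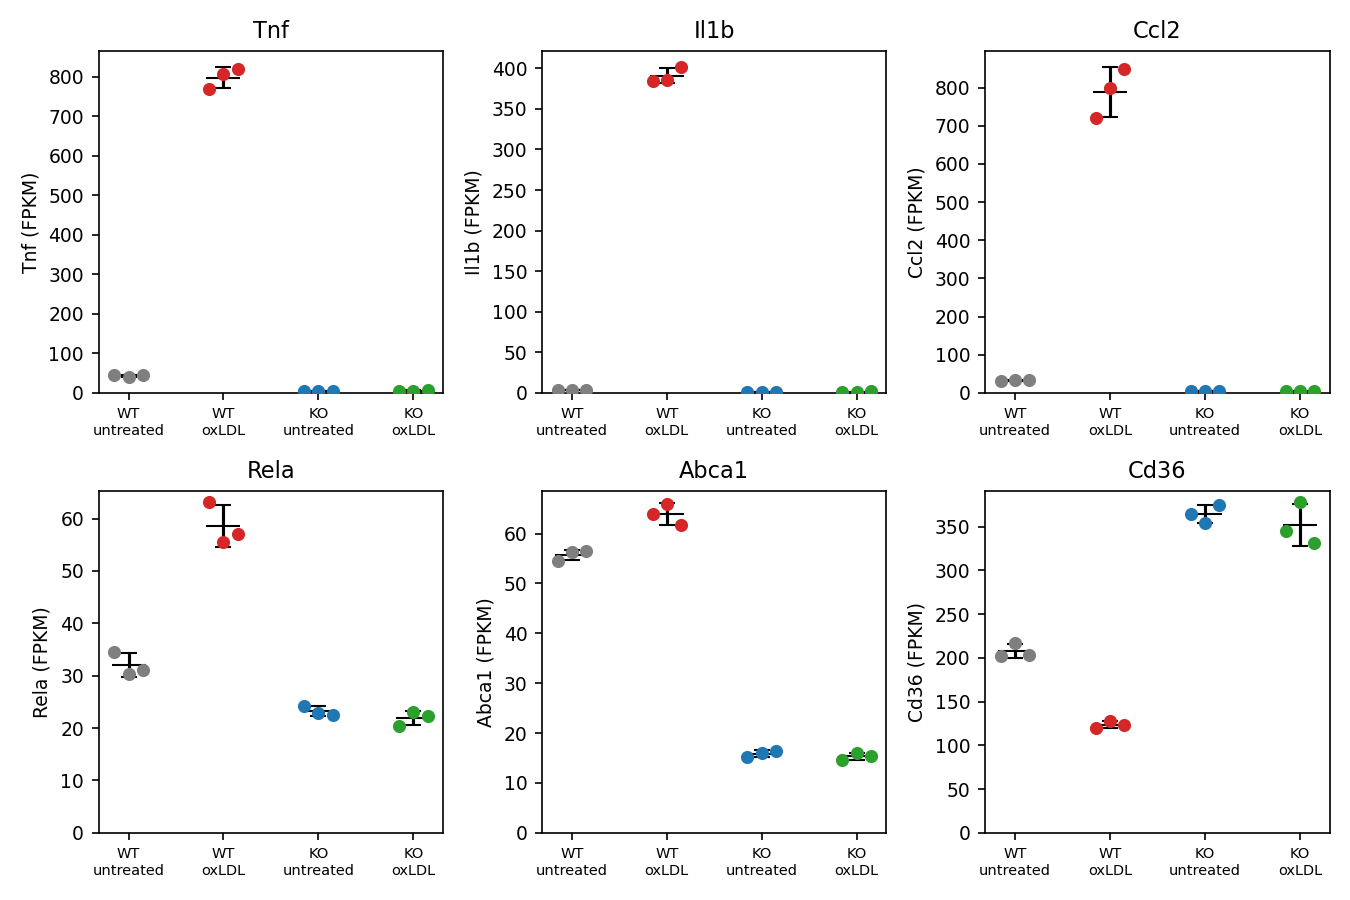
FPKM (vertical axes, linear) of Tnf, Il1b, Ccl2, Rela, Abca1 and Cd36 in each library of the 4 groups (horizontal axes); points are libraries, with the mean ± SD of 3. Tnf averages 798 FPKM in WT with oxLDL against 44 FPKM in untreated WT, and the KO groups lie below both.

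The second comparison asked what oxLDL changed in KO macrophages, and 2 genes were called. Nphp4, which encodes a protein of primary cilia, rose from 0 counts in untreated KO to 119 counts in KO with oxLDL, at least 39.1-fold, and it had 122 counts in untreated WT and 37 in WT with oxLDL. Ssbp4, which encodes a single-stranded DNA binding protein, rose from 2.74 ± 0.16 to 6.29 ± 0.38 FPKM (SD, n = 3), a log2 change of 1.19 ± 0.16 (SE). The inflammatory genes did not pass: Tnf was at 0.42 (edgeR adjusted p = 0.335), Il1b at 0.64 (adjusted p = 0.753), Il6 at 2.37 (adjusted p = 0.67), Ccl2 at 0.18 (adjusted p = 0.709) and Rela at -0.08 (adjusted p = 0.929). Single libraries set the Il1b and Il6 values: Il1b was at 0.04 without KO replicate 3 with oxLDL, and Il6 had 0, 0 and 10 counts untreated and 0, 19 and 35 with oxLDL. Nfkb1 was at -0.06, Cd36 and Abca1 both at -0.05, Plin2 at -0.04 and Wee1 at -0.11, and none of them passed. The next smallest p-values in the upward direction belonged to Col5a3 (a collagen gene, 0 and 63 counts), Uqcrq (a respiratory chain gene, 1.28 ± 0.20) and Socs1 (a cytokine signalling brake, 0 and 22 counts), with edgeR adjusted p between 0.0576 and 0.06. Downward, they belonged to 4930404N11Rik (-5.73 ± 0.90), Gm37240 (-9.17 ± 2.0), Gfpt2 (-0.79 ± 0.18), Hectd2 (-0.83 ± 0.19) and Dusp14 (33 and 0 counts), none of which passed. With 1 library left out, Col5a3 passed without KO replicate 1 with oxLDL, Socs1 without KO replicate 2 with oxLDL and Gm37240 without untreated KO replicate 3, at edgeR adjusted p of 0.02, 0.0395 and 0.0453.

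No member of any of the 35 lists was called with oxLDL in KO over all genes tested. Adjusted over the list alone, 3 of 29 cytokines and chemokines, 4 of 22 efflux genes and 6 of 37 NF-κB feedback targets were higher, and 2 feedback targets were lower. On the same basis 2 of 13 WEE1 and cyclin-dependent kinase regulators, 2 of 20 efferocytosis genes and 1 gene in each of 9 other lists were higher, the interferon-stimulated genes among these lists. Camera placed the cytokines and chemokines (adjusted p = 9.27e-08), the interferon-stimulated genes (adjusted p = 9.82e-05), the NF-κB feedback targets (adjusted p = 0.00992) and the WEE1 and cyclin-dependent kinase regulators (adjusted p = 0.00496) above other genes and the mitochondrially encoded genes below them (adjusted p = 0.000113). With an estimated correlation these were adjusted p = 0.157, 0.356, 0.157, 0.0822 and 0.378. The median fitted change of the cytokines and chemokines was 0.28 log2 and that of the interferon-stimulated genes 0.07. Both calls came from edgeR's quasi-likelihood test (adjusted p = 0.0349 each), and 1211 genes had an unadjusted p under 0.05. DESeq2 called 110 genes, 99 of them up, and limma on FPKM called 0. The groups did not overlap for 2320 genes (13.4%, against 10% by chance), and leaving out 1 library gave 0 to 3 calls, with 0 without untreated KO replicate 1, untreated KO replicate 2 or KO replicate 3 with oxLDL. Ssbp4 no longer passed without any 1 of the 6 KO libraries (1.14 to 1.24), nor Nphp4 without untreated KO replicate 1, 2 or 3 or KO replicate 3 with oxLDL (edgeR adjusted p of 0.0594 to 0.116).

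The third comparison asked how KO macrophages differed from WT before any oxLDL, and inflammatory and interferon genes were lower in KO. Tnf was lower in KO, with a log2 difference of -3.30 ± 0.11 (SE, n = 3 against 3), as were Ccl2 (-2.64 ± 0.08), Il1b (-2.34 ± 0.28) and Il6 (-4.05 ± 0.80). The untreated KO libraries had 0, 0 and 10 Il6 counts, so the size of its difference rests on 1 library, although it passed with any 1 of the 6 libraries left out. Rela (-0.36) and Nfkb1 (-0.56) were lower as well. Cd36 (0.92 ± 0.05) and Plin2 (0.64 ± 0.04) were higher in KO, and Abca1 was lower (-1.71 ± 0.04). The guanylate binding protein gene Gbp11, part of the interferon response, had 892 counts in WT and 0 in KO, at least 302-fold lower. Ly6i (-9.05 ± 0.43), Cd300e (-8.87 ± 0.48), an activating monocyte receptor, and Iigp1 (-7.24 ± 0.23), a GTPase against intracellular parasites, were also far lower. Other large differences were in Serpina3f (-6.90), Art2b (-6.83), Gbp4 (-6.69) and Timd4 (-6.57 ± 0.62), a receptor for apoptotic cells. Tceal7 (4.56 ± 0.35), the glycosyltransferase gene B3gnt7 (4.45), Mamdc2 (4.41 ± 0.09), the angiotensin-converting enzyme gene Ace (3.92), the secretory protein gene Scgb1a1 (3.88) and the cell cycle inhibitor gene Cdkn1c (3.84) were higher in KO, as were Awat1 (4.99) and Sfrp5 (4.89).

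All 43 interferon-stimulated genes were lower in untreated KO, the same adjusted over the list alone (camera adjusted p = 5.17e-215, and 0.000122 with an estimated correlation), with Ifit2 at -6.22 ± 0.15 and Ifit3 at -5.81. Of 29 cytokines and chemokines 25 were lower and 0 higher (25 and 1 adjusted over the list alone; camera adjusted p = 3.61e-25, and 0.0195 with an estimated correlation). Csf3 went from 122 counts to 0, at least 41.4-fold lower, and Cxcl9, a T cell attractant, was at -5.42. Of 37 NF-κB feedback targets 30 were lower and 2 higher (camera adjusted p = 1.83e-39, and 0.000195 with an estimated correlation). Marcksl1 (-4.49) and Irf1 (-3.56) were lower, and Cd83 (0.81) and Rel (0.30) were higher. Of 32 pathway components 15 were lower and 4 higher, or 15 and 5 adjusted over the list alone (camera adjusted p = 0.00034, and adjusted p = 0.0687 with an estimated correlation), with Tlr2 at -2.64 and Ticam1 at 0.63. Of 14 inflammasome genes 8 were lower and 2 higher (camera adjusted p = 3.72e-06, and 0.00744 with an estimated correlation), with Mefv at -3.24 and Txnip at 0.82. Of 10 class II antigen presentation genes 5 were lower and 2 higher (camera adjusted p = 0.215), with the regulator Ciita at -1.52 and Cd74 at 0.54.

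Lipid synthesis and storage genes tended to be higher in untreated KO. Of 24 cholesterol biosynthesis genes 17 were higher and 0 lower, or 18 and 0 adjusted over the list alone (camera adjusted p = 4.29e-06, and 0.0285 with an estimated correlation), with Sc5d at 1.08 and Dhcr7 at 0.94. Of 12 fatty acid synthesis genes 9 were higher and 2 lower (camera adjusted p = 0.0368, and adjusted p = 0.338 with an estimated correlation), with Scd1 at 1.02 and Acss2 at -1.24. Of 26 PPAR and lipid storage genes 15 were higher and 4 lower, or 17 and 4 adjusted over the list alone (camera adjusted p = 0.00312, and adjusted p = 0.0793 with an estimated correlation). Mgll (2.44), which releases fatty acids, and Pparg (1.91) were higher and Acsl1 (-3.53), which activates fatty acids, was lower. Of 22 efflux genes 11 were higher and 5 lower, or 11 and 6 adjusted over the list alone (camera adjusted p = 0.102), with the exporter gene Abcg1 at 1.30 and Ch25h at -2.54. Of 16 scavenger genes 6 were higher and 6 lower (camera downward, adjusted p = 0.00265, and adjusted p = 0.0687 with an estimated correlation), with Marco at -5.07 ± 0.12 and Lrp1 at 0.89.

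Markers of macrophages, and some of those of other cell types, differed as well. Of 19 macrophage core genes 12 were lower and 7 higher in untreated KO (camera downward, adjusted p = 6.22e-06, and 0.0416 with an estimated correlation), with the Fc receptor gene Fcgr1 at -2.03, the complement receptor gene C5ar1 at -1.84 and the transcription factor gene Cebpa at 1.08. Of 18 T and NK cell genes 11 were lower and 1 higher, or 12 and 1 adjusted over the list alone (camera adjusted p = 0.176): the granzyme gene Gzmb (288 counts in WT, 0 in KO, at least 97.7-fold) and Ncr1, an NK cell receptor gene (253 and 0, at least 85.8-fold), were lower, and the cytokine receptor gene Il7r was higher (1.49). Of 9 mast cell genes 7 were lower and 0 higher, or 8 and 0 adjusted over the list alone, with the tryptase genes Tpsab1 at -3.34 and Tpsb2 at -2.37. Of 8 neutrophil genes 5 were lower and 2 higher, with Lcn2, which binds bacterial iron carriers, at -5.50 and Cxcr2 at 4.49. Of 17 B cell genes 2 were lower and 2 higher, or 2 and 1 adjusted over the list alone, with Igkc at -1.83 and Cd22 at 1.07. Of 18 genes of monocyte-derived macrophages 9 were lower and 7 higher, with Ly6c2 at -5.13 ± 0.14 and the eosinophil-type ribonuclease gene Ear2 at 2.82, and of 17 mesothelial and fibroblast genes 4 were lower and 0 higher, with Col1a1 at -0.87 and Dcn at -0.78. Camera passed none of these lists but the macrophage core genes, with adjusted p = 0.123 for mast cells, 0.29 for neutrophils, 0.704 for B cells, 0.28 for monocyte-derived macrophages and 0.843 for mesothelium and fibroblasts. The B cell and the mesothelial and fibroblast lists, with 4 of 17 genes called in each, lay below the 31% called among all genes. Of 15 mitochondrially encoded genes 13 were higher and 1 lower in untreated KO (camera upward, adjusted p = 0.0106, and adjusted p = 0.535 with an estimated correlation), against 10 higher and 1 lower with library totals alone and 3 higher and 1 lower with quantile normalization. With oxLDL 11 were higher and 2 lower in KO (camera adjusted p = 0.507). The 24 tested large peritoneal macrophage genes had a median log2 difference, KO against WT, of -0.45 untreated and 0.26 with oxLDL.

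In the test of KO against WT without oxLDL, edgeR's quasi-likelihood test called 5359 genes, 2559 higher and 2800 lower in KO, and 1739 differed by at least 2-fold, 537 higher and 1202 lower. The adjusted p was 1.1e-11 for Tnf, 1.8e-12 for Ccl2, 0.00116 for Il6, 0.000738 for Rela, 9e-10 for Cd36 and 4.76e-13 for Abca1 in edgeR's test. The groups did not overlap for 7764 genes (44.9%, against 10% by chance). Of the called genes 47.8% were higher with TMM, 31.5% with library totals alone and 61.2% with quantile normalization, and neither Il6 (-0.13) nor Csf3 (-0.26) passed with quantile normalization.

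The fourth comparison asked how the genotypes differed in the presence of oxLDL, and the same inflammatory groups were lower in KO by larger amounts. The log2 difference of KO against WT was -7.47 ± 0.13 for Tnf (SE, n = 3 against 3), -8.83 ± 0.27 for Il1b, -9.06 ± 0.42 for Il6 and -7.44 ± 0.09 for Ccl2. It was -1.72 for Rela and -2.48 for Nfkb1. Cd36 (1.21) and Plin2 (0.74) were higher in KO and Abca1 was lower (-2.36). Gbp11 had 3111 counts in WT and 0 in KO, at least 1440-fold lower. Gzmb and Pla1a, a phospholipase gene, each had 966 counts in WT and 0 in KO, at least 448-fold lower, and Hrc (960 and 0) and Gbp2b (894 and 0) were at least 445-fold and 415-fold lower. Klri1 (at least 188-fold) and Rnase10 (at least 184-fold) had 0 counts in KO, and U90926, a non-coding transcript, was at -11.35 ± 0.43 with 4 counts in KO. In the other direction, 4 of the genes named for the largest rises had 0 counts in WT: Ramp1, a subunit of neuropeptide receptors (957 counts in KO, at least 229-fold), Sigirr, which dampens interleukin-1 and Toll-like receptor signalling (918 counts, at least 220-fold), Sfrp5, a WNT antagonist (737 counts, at least 177-fold) and Awat1, a wax ester synthase (389 counts, at least 93.2-fold). Galnt9 (8.50 ± 0.35), Tceal7 (7.02) and Cd28 (6.70 ± 0.12), a costimulatory receptor of T cells, were also higher, and Trav14n-3 had 478 counts in KO and 2 in WT, a ratio of 172 (95% counting interval 47.3 to 1420).

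With oxLDL, 29 of 29 cytokines and chemokines, 37 of 37 NF-κB feedback targets and 43 of 43 interferon-stimulated genes were lower in KO, the same adjusted over the list alone. Camera gave adjusted p = 9.64e-37, 2.86e-67 and 1.71e-135, and with an estimated correlation adjusted p = 0.000721, 4.26e-05 and 0.000721. Cd40 was at -6.96, Marcksl1 at -7.46, Ifi44 at -8.66 and Mx1 at -7.96. Of 32 pathway components 26 were lower and 4 higher (camera adjusted p = 9.4e-13, and 0.00326 with an estimated correlation), with Tlr2 at -4.15 and Cd14 at -4.13. Of 14 inflammasome genes 9 were lower and 5 higher (camera adjusted p = 2e-04, and 0.0221 with an estimated correlation), with Mefv at -6.25, Nlrp3 at -4.86 and Nlrp1b at 4.58. Of 23 immediate early and heat shock genes 15 were lower and 2 higher, or 16 and 2 adjusted over the list alone (camera adjusted p = 0.00137, and 0.0416 with an estimated correlation), and 6 of 10 class II genes were lower and 2 higher. Of 24 cholesterol biosynthesis genes 20 were higher and 2 lower (camera adjusted p = 0.00167, and adjusted p = 0.106 with an estimated correlation), with Dhcr7 at 3.90. Of 12 fatty acid synthesis genes 9 were higher and 1 lower (adjusted p = 0.00553 by camera, and adjusted p = 0.173 with an estimated correlation), with Scd2 at 2.62 and Elovl5 at 2.14. Of 26 PPAR and lipid storage genes 17 were higher and 6 lower (adjusted p = 0.00411 by camera, and adjusted p = 0.0749 with an estimated correlation), with Pparg at 4.96, Cd300a at 3.46, Dgat2 at -6.04 and Acsl1 at -5.36. Of 22 efflux genes 12 were higher and 6 lower (adjusted p = 0.00992 by camera, and adjusted p = 0.167 with an estimated correlation), with Cyp27a1 at 2.74 and Ch25h at -8.16. Of 16 scavenger genes 7 were higher and 8 lower (adjusted p = 0.0294 by camera, and adjusted p = 0.144 with an estimated correlation), and of 28 NRF2 genes 7 were higher and 15 lower (adjusted p = 0.00992 by camera, and adjusted p = 0.338 with an estimated correlation). Of 19 macrophage core genes 8 were higher and 11 lower (adjusted p = 0.00411 by camera, and adjusted p = 0.157 with an estimated correlation), and of 18 T and NK cell genes 1 was higher and 11 lower, or 1 and 13 adjusted over the list alone.

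In this comparison edgeR's quasi-likelihood test called 10016 genes, 5286 higher and 4730 lower in KO, and 4934 differed by at least 2-fold, 2558 higher and 2376 lower. The adjusted p was 1.36e-15 for Tnf, 7.26e-17 for Ccl2 and 1.5e-11 for Rela in edgeR's test. The groups did not overlap for 10864 genes (62.8%, against 10% by chance). Of the called genes 52.8% were higher with TMM, 69.5% with library totals alone and 70.5% with limma on FPKM.

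**Figure D4:**
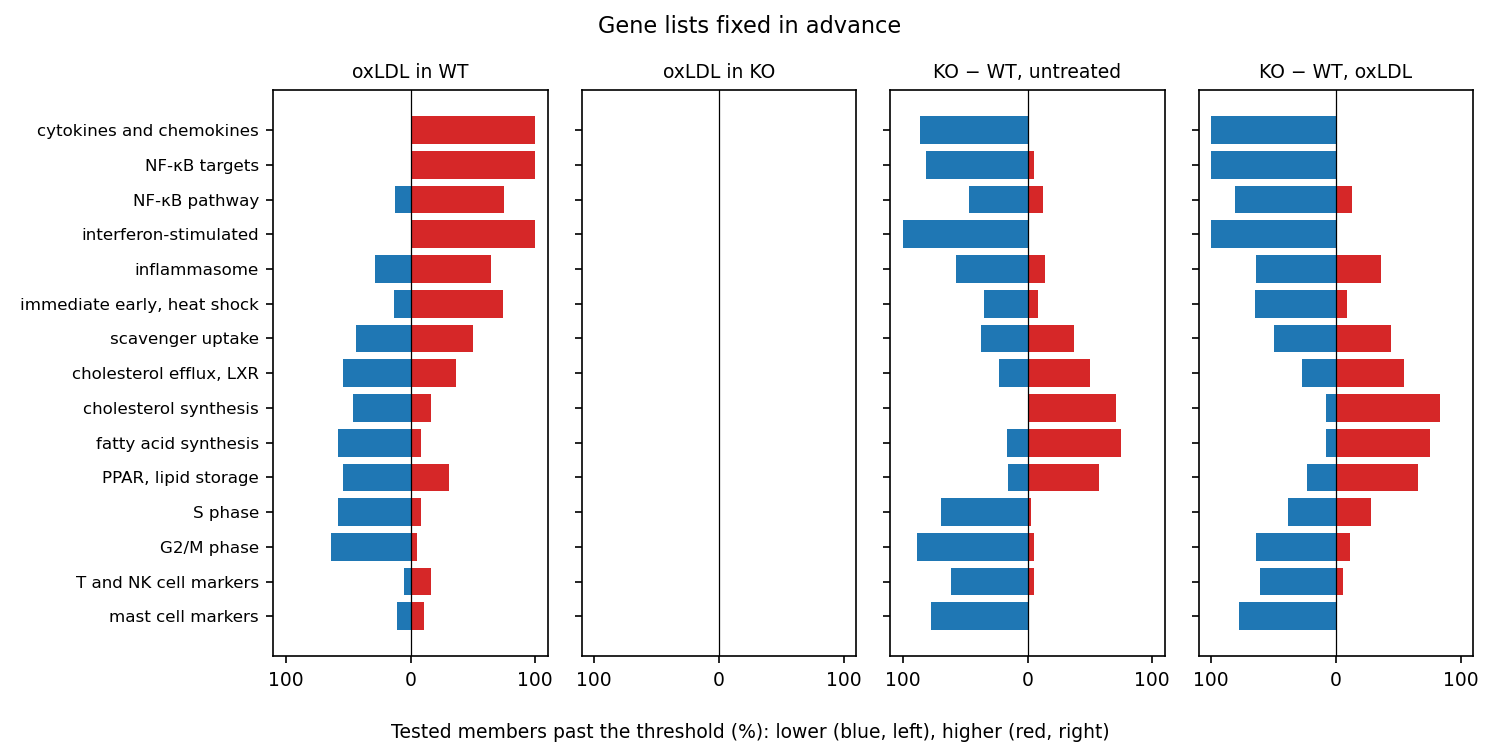
Percent of tested members that were higher (red) or lower (blue) at the threshold of edgeR's test, for 15 fixed gene lists (vertical axis) in 4 panels, one per comparison (horizontal axes in percent). All 43 interferon-stimulated genes rose with oxLDL in WT, 0 were called with oxLDL in KO, and all 43 were lower in KO than in WT.

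The fifth comparison tested whether the oxLDL change itself differed between genotypes, as the KO change minus the WT change. The difference was negative for Tnf (-4.17 ± 0.15 log2, SE), Il1b (-6.49), Ccl2 (-4.81), Rela (-1.36), Nfkb1 (-1.91) and Abca1 (-0.66), all of which rose with oxLDL in WT. It was positive for Cd36 (0.29), which fell in WT. It did not pass for Wee1 (0.40 ± 0.20, edgeR adjusted p = 0.14) or Plin2 (0.10, adjusted p = 0.228), although with library totals alone Wee1 passed at 0.81 and Plin2 at 0.51, and with limma on FPKM at 0.57 and 0.51. Il6 was at -5.02 ± 1.8 (edgeR adjusted p = 0.0335) and did not pass without untreated KO replicate 3 (-0.33) or without both WT replicate 2 libraries (-4.85), and Abca1 did not pass with quantile normalization (-0.14). The other large negative values belonged to Ptx3 (-7.29), a soluble pattern recognition protein, U90926 (-7.01), Nos2 (-6.98) and Edn1 (-6.83). The difference also passed, with no estimate of its size, for 4 of the named genes, which had 0 counts in KO with oxLDL: Nt5c1a (4 and 386 counts in WT without and with oxLDL, 16 in untreated KO), Hrc (48, 960 and 18), Gbp2b (105, 894 and 13) and Pla1a (92, 966 and 10). The large positive values belonged to Galnt9 (5.77), Slc27a6 (5.16) and St6gal1 (5.05). On the positive side 5 of the named genes, which had 0 counts in WT with oxLDL, passed, again with no estimate of size. These were Guca1a (273 counts in untreated WT, 0 and 317 in KO without and with oxLDL), Sigirr (152, 784 and 918), Ramp1 (99, 639 and 957), Sfrp5 (20, 637 and 737) and Awat1 (12, 418 and 389). With 1 library left out, Guca1a did not pass without untreated WT replicate 3 (edgeR adjusted p = 1), Gbp2b without untreated KO replicate 2 (0.0548), Pla1a without untreated KO replicate 3 (1) and U90926 without untreated KO replicate 1 (0.919). Awat1 did not pass in 10 of the 12 fits that left out 1 library (edgeR adjusted p of 0.0571 to 0.1), the exceptions being without untreated WT replicate 3 and KO replicate 2 with oxLDL. Its direction turned with limma on FPKM (-0.01), median-of-ratios (-0.02) and quantile normalization (-0.09). Guca1a and Sfrp5 did not pass with limma on FPKM, nor Sigirr with quantile normalization.

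In the interaction, 37 of 37 NF-κB feedback targets and 43 of 43 interferon-stimulated genes had a negative difference, the same adjusted over the list alone (camera adjusted p = 2.15e-67 and 2.62e-68, and 3.27e-05 and 0.00326 with an estimated correlation). Of 29 cytokines and chemokines 26 were negative and 0 positive, or 27 and 0 adjusted over the list alone (camera adjusted p = 1.84e-38, and 0.00217 with an estimated correlation). Of 32 pathway components 24 were negative and 3 positive, or 24 and 4 adjusted over the list alone (camera adjusted p = 1.15e-14, and 0.00217 with an estimated correlation), of 14 inflammasome genes 7 were negative and 4 positive (camera adjusted p = 0.0106, and adjusted p = 0.0749 with an estimated correlation), and of 23 immediate early and heat shock genes 15 were negative and 3 positive, or 15 and 4 adjusted over the list alone (camera adjusted p = 4.2e-05, and 0.016 with an estimated correlation). Among lipid lists, 13 of 22 efflux genes were positive and 5 negative (camera adjusted p = 0.00564, and adjusted p = 0.157 with an estimated correlation), 7 of 12 fatty acid synthesis genes were positive and 1 negative (camera adjusted p = 0.0144, and adjusted p = 0.262 with an estimated correlation), and 11 of 26 PPAR genes were positive and 7 negative, or 11 and 8 adjusted over the list alone (camera adjusted p = 0.0395, and adjusted p = 0.173 with an estimated correlation). Of 24 cholesterol biosynthesis genes 10 were positive and 3 negative (camera adjusted p = 0.247). By edgeR's quasi-likelihood test, 7217 genes passed, 3828 positive and 3389 negative, with an adjusted p of 4.27e-11 for Tnf, 2.92e-08 for Rela, 0.00244 for Cd36 and 5.28e-07 for Abca1. Of the called genes 53% were positive with TMM and 79.6% with library totals alone. Of the 3510 genes that changed at least 2-fold with oxLDL in WT, 2954 (84.2%) passed the interaction test.

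The oxLDL responses of the genotypes were then compared across all 17291 genes. The log2 changes of WT and KO had a Pearson correlation of 0.028 and a Spearman correlation of -0.004 across genes, and the slope of the KO change on the WT change over genes called in WT was 0.013. Leaving out 1 library gave correlations of 0.002 to 0.062, and genes with at least 5 FPKM gave 0.18. Of the genes raised in WT, 0 were among the 2 raised in KO, against 0.479 by n1 × n2 / N. The KO differences without and with oxLDL, which share no library, had a Pearson correlation of 0.622 and a Spearman correlation of 0.532, with 1947 shared higher genes (782.3 by n1 × n2 / N) and 2159 shared lower genes (765.9).

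Genes that oxLDL raised in WT were mostly lower in KO with oxLDL, and the reverse. Of the 4140 raised genes 3633 (87.8%) were called lower in KO with oxLDL (1133 by n1 × n2 / N), and of the 4708 lowered genes 4071 (86.5%) were called higher (1439 by n1 × n2 / N), 7704 in all. Both comparisons use the WT libraries with oxLDL, and the correlation across genes was -0.82 with a covariance of -2.455. In 100 simulations of unchanged groups, shared libraries alone gave a mean of 0.03 such genes (at most 1), a correlation of -0.522 and a covariance of -0.193. The shared group of 3 libraries was not split, since 1 part would hold a single library, so part of the excess may come from shared libraries. The difference with oxLDL equals the untreated difference plus the KO change minus the WT change. With a KO slope of 0.013, opposite signs largely follow from the WT response and are not a further result. The simulations hold no WT response, and n1 × n2 / N takes the comparisons as unrelated. Neither gives the count that this relation alone would produce. The genes raised in WT had a median log2 difference of -0.13 in untreated KO against untreated WT, 1579 of them lower and 527 higher, and the lowered genes a median of 0.11, 1400 higher and 507 lower.

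**Figure D5:**
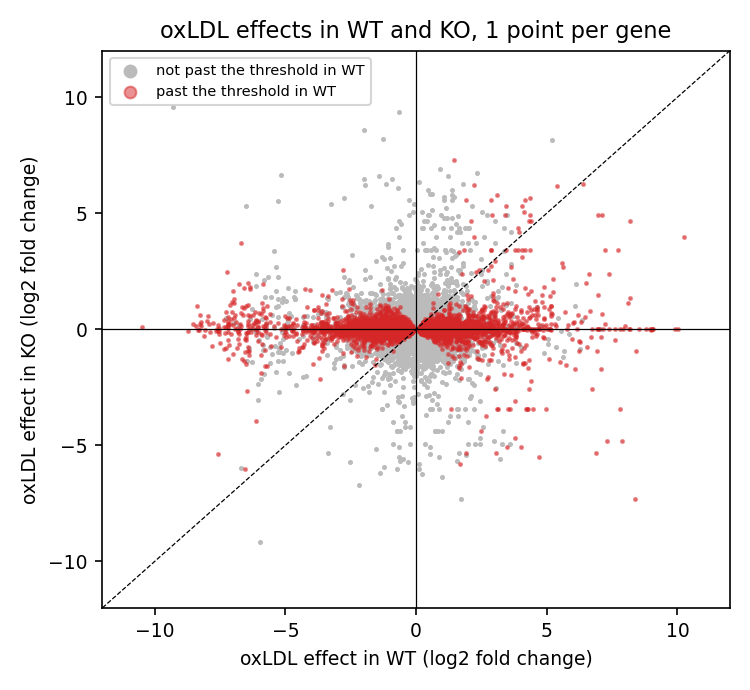
Log2 fold change with oxLDL in WT (horizontal axis) against that in KO (vertical axis), a point per tested gene; red points passed the threshold of edgeR's test in WT, and the dashed line marks equal change. The points spread along the WT axis and lie near 0 on the KO axis, with a slope of 0.013 over the red points.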

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

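The groups differed in their response to oxLDL by the interaction test, which is what brought the results of this part to attention. The tests on depth and spread, on missing oxLDL, on a prior oxLDL-like state, on macrophage share, on endotoxin and on scaling with library totals were chosen after the results were seen. The splits of the libraries and the tests on the shallower libraries and with DESeq2's size factors were chosen before.

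The oxLDL change differed between genotypes for 7217 genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The difference (KO change minus WT change, log2) was -1.36 for Rela, -1.91 for Nfkb1, -4.17 for Tnf, -6.49 for Il1b, -5.02 for Il6, -4.81 for Ccl2, 0.29 for Cd36 and -0.66 for Abca1. It was 5.77 for Galnt9, 5.16 for Slc27a6, 5.05 for St6gal1, -7.29 for Ptx3, -7.01 for U90926, -6.98 for Nos2 and -6.83 for Edn1. Genes with a group at 0 counts have no estimate of this difference, and their edgeR adjusted p was 0.013 for Guca1a, 7.56e-05 for Sigirr, 2.6e-06 for Ramp1, 0.0177 for Sfrp5, 0.0428 for Awat1, 0.000225 for Nt5c1a, 0.000103 for Hrc, 0.0088 for Gbp2b and 0.00353 for Pla1a. With 1 library left out, Il6 (-0.33 without untreated KO replicate 3), U90926, Guca1a, Gbp2b, Pla1a and Awat1 no longer passed in at least 1 fit. The list tests that passed gave camera adjusted p of 1.84e-38 for cytokines and chemokines, 2.15e-67 for NF-κB feedback targets, 1.15e-14 for pathway components, 0.0106 for the inflammasome, 2.62e-68 for interferon-stimulated genes and 4.2e-05 for immediate early genes. They gave 0.00564 for cholesterol efflux, 0.0144 for fatty acid synthesis, 0.0395 for PPAR genes, 0.0114 for NRF2 genes, 0.0426 for S phase and 0.0476 for glycolysis. With an estimated correlation, 7 of these 12 no longer passed, at an adjusted p of 0.0749 for the inflammasome, 0.157 for efflux, 0.262 for fatty acid synthesis, 0.173 for PPAR genes, 0.338 for NRF2 genes, 0.107 for S phase and 0.338 for glycolysis.

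With the libraries regrouped, the 2-group comparisons allow 10 splits each, too few for a share under 0.05. The real split of WT by oxLDL gave 8848 genes and the highest other 0, and was alone in giving as many (1 of 10). For KO by oxLDL the real split gave 2 genes and the highest other 2, so 2 of 10 splits gave as many. KO against WT gave 5359 genes untreated (highest other 1; 1 of 10) and 10016 with oxLDL (highest other 1; 1 of 10). For the interaction, 4 of 100 drawn splits, the real one included, gave at least 7217 genes, and the highest other gave 7344. All 15 drawn splits that parted the oxLDL libraries by genotype gave 5743 to 7344 genes and the 85 others at most 22. Splits that mix these libraries put the genotype difference into the spread within groups. Splits that part them carry that difference into the contrast. The regrouping therefore cannot decide on the interaction.

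The first pattern weighed is that oxLDL changed 2 genes in KO against 8848 in WT. Too little depth or too much spread in the KO libraries would leave the interaction undetected, yet 84.2% of the genes changed at least 2-fold in WT passed it, and the common dispersion fitted to the 6 libraries of each genotype alone was 0.027 in KO and 0.0289 in WT. KO cells already in the oxLDL state would hold WT-raised genes high before treatment, but their median difference in untreated KO was -0.13 (1579 lower and 527 higher). Both comparisons use the untreated WT libraries, and the effect of this sharing was not simulated. Chance deviations in those libraries would move this median upward. KO libraries labelled oxLDL (their titles say LDL) that received no oxLDL, or that hold untreated cells, could give the same slope of 0.013 as a lost response, and these cannot be told apart because no measure of exposure is in the table. A different mix of cell types in KO stays open as well and was not tested as a source of the missing response. The 18 tested T and NK cell genes had a median log2 difference, KO against WT, of -3.45 untreated and -3.98 with oxLDL. In these medians, genes with a group at 0 counts were set at their bound. A genotype effect on the response, which the design names, stays open, as does a weak response in KO. For the latter, DESeq2 called 110 genes (99 up), the correlation with the WT response was 0.18 among genes of at least 5 FPKM, and camera placed cytokines and chemokines upward (adjusted p = 9.27e-08, and adjusted p = 0.157 with an estimated correlation). On the other side, limma on FPKM called 0 genes, and only 1 of DESeq2's calls was among the 2 reported. Il1b had 273 counts in KO replicate 3 with oxLDL, against 78 and 135 in replicates 1 and 2, so 1 library weighs on the cytokines.

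The second pattern is the broad difference between untreated KO and WT, with 5359 genes. A lower share of macrophages in KO was predicted to raise the markers of the other cell types together. By fry's directional test 4 of 8 such lists were lower, among them T and NK cells (adjusted p = 5.34e-07) and mast cells (adjusted p = 7.27e-07), while 2 were higher and 2 did not pass (5 of the 114 listed genes are in another list too, and macrophages may express others). The lists therefore did not rise together. This cannot decide on the share of macrophages, since the other cell types need not change in the same direction. The shallower WT libraries may add to the spread, but 4743 genes were called without untreated WT replicate 2. A different mix of cell types in KO stays open. A genotype effect, and a difference between preparations or animals of the genotypes, stay open as well and were not tested, since each genotype may come from a single preparation. In the test of genotype with oxLDL the same limits hold.

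The third pattern is that inflammatory genes rose with oxLDL in WT while 44 of the 84 tested members of 4 lipid lists fell and 21 rose, none of these lists passing camera with an estimated correlation. Scaling does not account for the inflammatory rise, since 98.2% of the raised members of the 3 inflammatory lists (107 of 109) still rose with library totals alone, which moved the median gene downward. Scaling may account for the lower lipid genes: 95.5% stayed lower with DESeq2's size factors, but these differ from TMM by 0.0419 log2 and so test nothing, and library totals and quantile normalization do not move the median gene upward. Endotoxin in the oxLDL preparation could raise inflammatory genes without a lipid-loading response: 38.1% of the called efflux and PPAR members rose (16 of 42). But signalling of oxLDL itself through Toll-like receptors gives the same. These cannot be told apart because no measure of endotoxin is in the table. A response to oxLDL, as the labels state, stays open.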

How the results depend on the processing

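Limma on log2(FPKM + 1) was planned as the main test for a table without raw counts, and its use beside edgeR was not planned. The other alternatives were planned except library totals alone, the joint omission of both WT replicate 2 libraries, and the omission of libraries and the use of limma in the comparisons of fold changes, which were chosen after the data were seen. Outside oxLDL in KO, the counts of called genes stayed within 1.5 times of the reported ones under all alternatives except a minimum of 5 FPKM and a minimum fold. Similar counts did not mean the same genes. With library totals alone, 10544 genes were called for oxLDL in WT. Of these, 6930 were shared with the reported calls in the same direction and 429 were called in the opposite one. Opposite calls numbered 434 with limma on FPKM, 199 with quantile normalization and 0 with DESeq2. With limma on genes of at least 5 FPKM they were 4966 for oxLDL in WT, 3464 and 4968 for KO against WT untreated and with oxLDL, and 4559 for the interaction, where fewer genes were tested. With at least 2-fold change added they were 3510, 1739, 4934 and 3176, which is a stricter threshold by construction. With oxLDL in KO the count of 2 became 1 with no filter, 61 with only the 6 KO libraries, 110 with DESeq2, and 0 with an adjusted p under 0.01 and with limma on FPKM, its pseudocounts of 0.1 and 0.5, its minimum of 5 FPKM, the TPM scale, median-of-ratios, quantile normalization and robust eBayes. Leaving out 1 library gave 0 to 3, with 0 without untreated KO replicate 1 or 2 or KO replicate 3 with oxLDL. The cause was not tested. Of the list tests, 56 of 175 passed with camera, 23 with an estimated correlation and 121 with fry, which asks a different question. The correlation of the oxLDL responses was 0.028, and 0.18 among genes of at least 5 FPKM. That of the KO differences was 0.622, and 0.865 among genes of at least 5 FPKM, 0.794 with quantile normalization and 0.802 with limma; leaving out 1 library gave 0.583 to 0.617.

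Deviations from the group means over all genes tested gave no sign of pairing by replicate number. The 18 same-number pairs correlated at -0.045 to 0.031, none over 0.1, and 2 of 12 libraries correlated best with their own number. This cannot exclude shared handling by number, since WT replicate 2 was the shallowest library in both treatment groups. With the replicate block the counts were 8603, 0, 5056, 9767 and 6927, and with a block within genotype 8384, 1 and 6673 for oxLDL in WT, oxLDL in KO and the interaction. With the block 3 list tests no longer passed, which were efferocytosis in untreated KO (camera adjusted p = 0.0644), PPAR genes in the interaction (0.0583) and glycolysis in the interaction (0.0589).

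Of the values of named genes under the alternatives, 12156 kept their side of the threshold, and 1 of these, for oxLDL in KO, changed direction. A further 457 lost their call, 31 gained one and 58 reversed. A reversed value changed direction and passed in the reported fit, in the alternative or in both. With library totals alone, mt-Rnr2 and mt-Co1 reversed with oxLDL in WT (-0.10 and -0.21), as they did with limma on FPKM at any pseudocount, filter or with robust eBayes. They were at -0.06 and -0.17 on the TPM scale and at -0.09 and -0.21 with arrayWeights, and mt-Rnr2 was at -0.45 with quantile normalization. In KO against WT with oxLDL, mt-Rnr2 was at 0.05 in these settings, 0.04 on the TPM scale and 0.47 with quantile normalization, where mt-Rnr1 was at 0.31, and Hsd17b7 was at 0.01 with arrayWeights. In the interaction, mt-Rnr2 was at 0.03 (0.39 with quantile normalization), mt-Nd5 at 0.06 (0.02 on the TPM scale, 0.24 with quantile normalization, 0.05 with arrayWeights) and Cd74 at 0.21 with quantile normalization. Awat1 in the interaction was at -0.01 with limma on FPKM, -0.02 with median-of-ratios and -0.09 with quantile normalization or arrayWeights. Dgat2 in untreated KO was at 0.05 with quantile normalization. The cause was not tested. Depth limits the genes with a group at 0 counts, whose differences have no estimate.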

Other observations

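Cell cycle genes, not described above, were mostly lower in untreated KO than in WT, and stress lists went both ways with oxLDL in WT. Of 36 S phase genes, which act in DNA replication, 21 fell and 3 rose with oxLDL in WT (camera downward, adjusted p = 0.0464, and adjusted p = 0.119 with an estimated correlation), with the transcription factor gene E2f2 at -2.63 log2 and the cyclin gene Ccne1 at 1.22. In untreated KO against WT, 25 were lower and 1 higher, or 26 and 1 adjusted over the list alone (camera adjusted p = 0.0144, and adjusted p = 0.0687 with an estimated correlation), with E2f7 at -3.46 and Pcna at 0.28. With oxLDL, 14 were lower and 10 higher in KO, or 14 and 12 adjusted over the list alone (camera adjusted p = 0.867). Of 36 G2/M genes 23 fell and 2 rose with oxLDL in WT (camera adjusted p = 0.0778), with Bub1b at -1.43 and the proliferation marker Mki67 at 1.15. In untreated KO 32 were lower and 2 higher, or 33 and 3 adjusted over the list alone (camera adjusted p = 3.88e-06, and 0.0272 with an estimated correlation), with Mki67 at -2.23 and Birc5 at -2.11, and with oxLDL 23 were lower and 4 higher, or 24 and 4 adjusted over the list alone (camera adjusted p = 0.431). Of 13 WEE1 and cyclin-dependent kinase regulators 4 rose and 4 fell with oxLDL in WT, with Ccnd2 at 3.31, the inhibitor gene Cdkn1a at 1.54 and the phosphatase gene Cdc25b, which opposes WEE1, at -2.12. In untreated KO 6 were lower and 0 higher, or 6 and 2 adjusted over the list alone, with Cdc25c at -1.91. Of 30 p53 and DNA damage genes 8 rose and 13 fell with oxLDL in WT (camera adjusted p = 0.786), with the death receptor gene Fas at 1.85 and Sesn1 at -2.96. Of 28 unfolded protein and integrated stress response genes 10 rose and 10 fell (camera adjusted p = 0.843), with Chac1 at 3.71 and Eif2ak3 at -1.26.

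Among macrophage functions with oxLDL in WT, 13 of 28 glycolysis and hypoxia genes rose and 7 fell (camera upward, adjusted p = 0.0368, and adjusted p = 0.309 with an estimated correlation), with the glycolysis regulator Pfkfb3 at 2.27 and Vegfa at -1.91. Of 21 alternative activation genes 8 rose and 7 fell, with Il10 at 4.35, Socs3 at 3.98 and the lectin gene Mgl2 at -1.93. Of 20 efferocytosis genes, which serve the uptake of dead cells, 5 rose and 12 fell, with Axl at 2.85 and Stab2 at -3.34. Of 28 matrix protease genes 11 rose and 9 fell, with the collagenase gene Mmp13 at 4.59 and the inhibitor gene Timp2 at -1.93. In untreated KO 11 of these were higher and 11 lower, with the cathepsin gene Ctsl at 1.84 and Mmp2 at -5.41. Of 19 macrophage core genes 10 rose and 7 fell with oxLDL in WT, with Fcgr1 at 2.09, and of 24 large peritoneal macrophage genes 3 rose and 8 fell, with Fabp4 at -2.06. Of 15 mitochondrially encoded genes 2 rose and 1 fell, and with library totals alone 0 rose and 14 fell, with mt-Rnr2 (0.30) and mt-Co1 (0.19) reversed. Of 15 housekeeping genes 6 rose and 6 fell, with Actb at 1.70 and Tfrc at -2.12. In the lists with few tested members, 1 of 2 eosinophil genes fell with oxLDL in WT, as did 1 of 2 platelet and erythroid genes, and of 10 dendritic cell genes 4 rose and 1 fell. Of 8 neutrophil genes 5 rose and 2 fell, or 5 and 3 adjusted over the list alone (fry upward, adjusted p = 1.4e-05; camera adjusted p = 0.327). Of 18 genes of monocyte-derived macrophages 8 rose and 4 fell (fry upward, adjusted p = 1.1e-06; camera adjusted p = 0.231). Of 17 B cell genes 3 rose and 3 fell, or 2 and 3 adjusted over the list alone, of 18 T and NK cell genes 3 rose and 1 fell, of 9 mast cell genes 1 rose and 1 fell, and of 17 mesothelial and fibroblast genes 3 rose and 1 fell, or 3 and 0 adjusted over the list alone. These B cell, T and NK cell, mast cell and mesothelial counts lie below the 51.2% called among all genes. In KO against WT with oxLDL, 7 of the 9 mast cell genes were lower and 0 higher (camera adjusted p = 0.416).

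Ifng, the gene of interferon-γ, which NK and T cells make, was chosen after its values were seen. Its counts were 71, 48 and 47 in untreated WT, 1508, 1200 and 1423 in WT with oxLDL, 8, 0 and 2 in untreated KO and 0, 0 and 4 in KO with oxLDL. No hypothesis about it was tested.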
